A study of Mus musculus with 24 samples.

How the data were processed

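The data are Affymetrix mouse gene array measurements of 12 RNA samples, 2 from each of 6 groups: undifferentiated ES cells, embryonic bodies, cardiac bodies, and whole hearts at E17.5, at P1 and in adults. Per the labels' protocols, ES cells were differentiated toward cardiomyocytes in a serum-containing medium, hearts were taken at E17.5 and P1, TRIzol was used for extraction, and after ribosomal RNA reduction and amplification the fragmented, biotin-labelled cDNA was hybridized. Each sample was deposited 2 times, as gene-level values of 35556 transcript clusters and as exon-level values of 241576 probe sets, 24 sets of values in all. Per the submitters' processing notes, the authors made the deposited log2 values with RMA in Affymetrix Power Tools, whose versions are not given in the sources used here. The values were used on that scale without further normalization.

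Gene symbols came from the platform annotation. Of the transcript clusters 21789 had 1 symbol, 1621 had several and 12146 had none, and of the probe sets the numbers were 212097, 4475 and 25004. Features with several symbols or none were left out of the tests, because their signal cannot be given to 1 gene. Old symbols were brought to current ones by Entrez number or synonym. For the 1015 genes with more than 1 transcript cluster the cluster with the highest mean was used, giving 19920 genes. Of the probe sets 205421 belonged to a tested gene; the exon-level test used the 15108 genes with at least 4 probe sets. The 218 probe sets whose values were identical to those of their gene were left out, a choice made after the data were seen.

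Gene-level values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays with 6 group means, which left 6 residual degrees of freedom and a prior of 6.2. There were 7 comparisons: embryonic bodies minus ES cells, cardiac bodies minus embryonic bodies, cardiac bodies minus ES cells, P1 minus E17.5, adult minus P1, adult minus E17.5, and cardiac bodies minus E17.5 hearts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The splicing index was fitted the same way and called at an adjusted p under 0.05 with a change of at least 1. Both groups had to have the gene at or above the median level (percentile 50), and at least 1 group the probe set. All p-values of single genes and probe sets are from moderated t tests, which pool the spread over genes and groups. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 168 pairs of list and comparison, and repeated with an estimated correlation. Of 587 list entries 552 were measured. Chance counts of shared gene calls were also summed within 20 bins of mean level, added after the data were seen. Signals were not tested against background. Whether the exon calls fell more often in alternatively spliced heart genes was tested with Fisher's exact test. Figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and input files were read with the R package data.table (version 1.17.8).

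The groups, comparisons, gene lists, thresholds and the rule for naming genes were set before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes with both arrays of one group above both of the other. It added up to 4 called members of each list and a fixed set of genes whatever their result. At exon level it took the 8 called probe sets with the largest change, 1 per gene, and up to 6 called probe sets of alternatively spliced heart genes.

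The procedure was tested on simulated data with 200 changed genes or probe sets. At gene level, for P1 minus E17.5, 2% of changes of 0.5, 50% of changes of 1 and 98% of changes of 2 were found, with 9 false calls among 133. At exon level, for adult minus E17.5, 0% of changes of 1, 28% of changes of 2 and 87% of changes of 3 were found, with 2 false calls among 103. The number of arrays therefore limits the precision. These rates apply where few features change, as in the simulation, and there smaller changes are mostly missed. Real comparisons with many calls had a looser cutoff, such as adult minus E17.5 with 18234 probe sets at an adjusted p under 0.05. Their recovery was not simulated.

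Alternatives at gene level were the replicate number as a block, only genes at or above the median in at least 1 group, quantile normalization, an intensity trend in the prior, the mean of all transcript clusters of a gene, the median of its exon-level values, and each array left out in turn. At exon level they were the replicate block, no filter on level, a filter at the 70th percentile, only genes whose level changed by at most 1, diffSplice, the median of the other probe sets of the gene in place of the gene level, and each array left out. Replicate numbers gave no steady pairing of samples across groups. Over 15 pairs of groups, the replicate deviations correlated across genes at r from -0.1762 to 0.2898. The highest was between E17.5 and P1 hearts, then 0.1685 between ES cells and cardiac bodies. A shared replicate component was not excluded for these pairs. Positions of probe sets within genes were not analysed here, so exons are not named.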

Results

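RNA from 12 samples of mouse cells and hearts was measured on Affymetrix mouse gene arrays, 2 samples in each of 6 groups. The cultured groups were undifferentiated embryonic stem (ES) cells at day 0, embryonic bodies (EB, the cell aggregates that differentiating ES cells form) at day 7, and cardiac bodies (CB, cultures carried further toward cardiomyocytes) at day 14. The tissue groups were whole hearts of E17.5 embryos, of pups at postnatal day 1 (P1) and of adults. Each array was given at gene level, as 35556 transcript clusters, and at exon level, as 241576 probe sets. The series asks how gene expression and alternative splicing change while the heart develops and while cardiomyocytes form in culture. Median log2 signals per array ran from 5.62 to 5.76 at gene level and from 6.40 to 6.53 at exon level. Across genes, which are not independent replicates, the 2 arrays of a group correlated at r = 0.993 in ES cells, 0.983 in EB, 0.990 in CB, 0.992 at E17.5, 0.971 at P1 and 0.984 in adults. The first principal component held 61.8% of the variance and ordered the groups as ES cells, EB, CB, E17.5, P1 and adult hearts. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures or animals. Changes are log2 differences between group means ± the standard error of the fit, with n = 2 arrays per group.

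The comparison of embryonic bodies with ES cells asks which genes change as ES cells begin to differentiate. Pou5f1 (transcript cluster 10444853), which encodes the pluripotency factor Oct4, fell by 3.34 ± 0.20 (adjusted p = 5.02e-07), from a mean log2 signal of 11.83 to 8.49. Nanog, another factor of the pluripotent state, fell by 3.25 ± 0.17 (adjusted p = 2.3e-07). Of 29 measured pluripotency genes, 23 fell and 6 were not called; adjusted over the list alone, 26 fell. The list's median change was -2.69, and camera gave an adjusted p of 4.81e-26, with 0.0232 as the adjusted p with an estimated correlation. Igf2, a fetal growth factor, rose by 5.91 ± 0.41 (adjusted p = 1.31e-06), from 5.84 to 11.74. It was 1 of 13 fetal growth and imprinted genes that rose among 16 measured, with Peg3 up by 4.01 ± 0.45 and Ndn by 3.17 ± 0.19. Adjusted over the list alone, 13 rose and 1 fell, and the camera adjusted p was 1.34e-10, or adjusted p = 0.0311 with an estimated correlation. Has2, which makes hyaluronan, rose by 5.68 ± 0.33, and Acta2, smooth muscle actin, by 5.49 ± 0.32.

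Some markers of epithelium, vessels and cardiac progenitors rose in embryonic bodies. Krt8 and Krt18, the keratins of simple epithelia, rose by 3.98 ± 0.18 and 4.90 ± 0.24, and 8 of 16 epithelial markers rose, 8 also when adjusted over the list alone. The camera adjusted p of that list was 3.07e-05, but adjusted p = 0.112 with an estimated correlation. The vascular receptor gene Kdr rose by 3.70 ± 0.26 and the endothelial cadherin gene Cdh5 by 3.06 ± 0.28, while Pecam1 fell by 1.43 ± 0.26. In all, 8 endothelial markers of 17 rose and 2 fell, counts that held when adjusted over the list alone (camera adjusted p = 0.00174; adjusted p = 0.391 with an estimated correlation). Of these 17 markers 6 were higher by over 1 in EB replicate 2 than in EB replicate 1. Among 24 cardiac transcription factors 12 rose, or 13 adjusted over the list alone, with Isl1 up by 3.24 ± 0.27 and Gata6 by 2.85 ± 0.29 (camera adjusted p = 1.16e-06; adjusted p = 0.12 with an estimated correlation); 5 of the 24 were higher by over 1 in EB replicate 1 and 4 in EB replicate 2. Nkx2-5, a factor of committed cardiac cells, changed by -0.06 ± 0.25 and was not called. Of 33 sarcomere genes 11 rose and 1 fell, also when adjusted over the list alone, and 7 rose without ES replicate 2 (camera adjusted p = 0.0203; adjusted p = 0.664 with an estimated correlation). Tpm1 (tropomyosin) rose by 3.28 ± 0.20 and Tnnc1 (troponin C) by 2.44 ± 0.21, while Myh6, the alpha myosin heavy chain of heart muscle, changed by 0.11 ± 0.21 and was not called.

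The 2 EB arrays differed in erythroid genes: Hbb-y, an embryonic globin, was at 11.32 in replicate 1 and 5.88 in replicate 2. Of 11 erythroid markers 4 rose and 1 fell against ES cells, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.69 with an estimated correlation). The rise count was 0 without ES replicate 1 or ES replicate 2, 1 without EB replicate 1 and 9 without EB replicate 2. Of 19920 genes tested, 2388 rose and 1716 fell, 1375 and 784 of them by at least 2-fold. The 4104 called genes became 2507 without ES replicate 1 and 2384 without ES replicate 2.

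Alternative exon use was read from the splicing index, the log2 signal of a probe set minus that of its gene on the same array. Between embryonic bodies and ES cells, Vgll4, a cofactor of TEAD transcription factors, had 1 probe set (10547014) whose index rose by 3.42 ± 0.30 (adjusted p = 0.0271), with mean signals of 9.95 and 4.01. Vgll4 itself rose by 2.52, with means of 8.89 and 6.37, so the probe set moved with its gene. In Tnnt2, the cardiac troponin T gene, 1 probe set (10350186) rose in index by 2.28 ± 0.22 (adjusted p = 0.036), with means of 7.71 and 4.11. The gene rose as well, with means of 7.46 and 6.14, so the probe set lay close to its gene in embryonic bodies. The index of a Tpm1 probe set (10594673) fell by 3.20 ± 0.34 (adjusted p = 0.0387): its mean was 9.18 in EB and 9.10 in ES cells while the gene rose. None of these calls was made with the replicate number as a block, which left 0 calls in this comparison. In total 16 of 92860 probe sets were higher and 19 lower in index, in 28 genes, and 30 of these 35 lay in genes whose level changed by more than 1. The count was 159 without EB replicate 1, 1 without ES replicate 2 and 0 without any one of the other 10 arrays, and the highest adjusted p was 0.163 for Vgll4 and Tnnt2 and 0.212 for Tpm1, each without EB replicate 2.

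**Figure D1:**
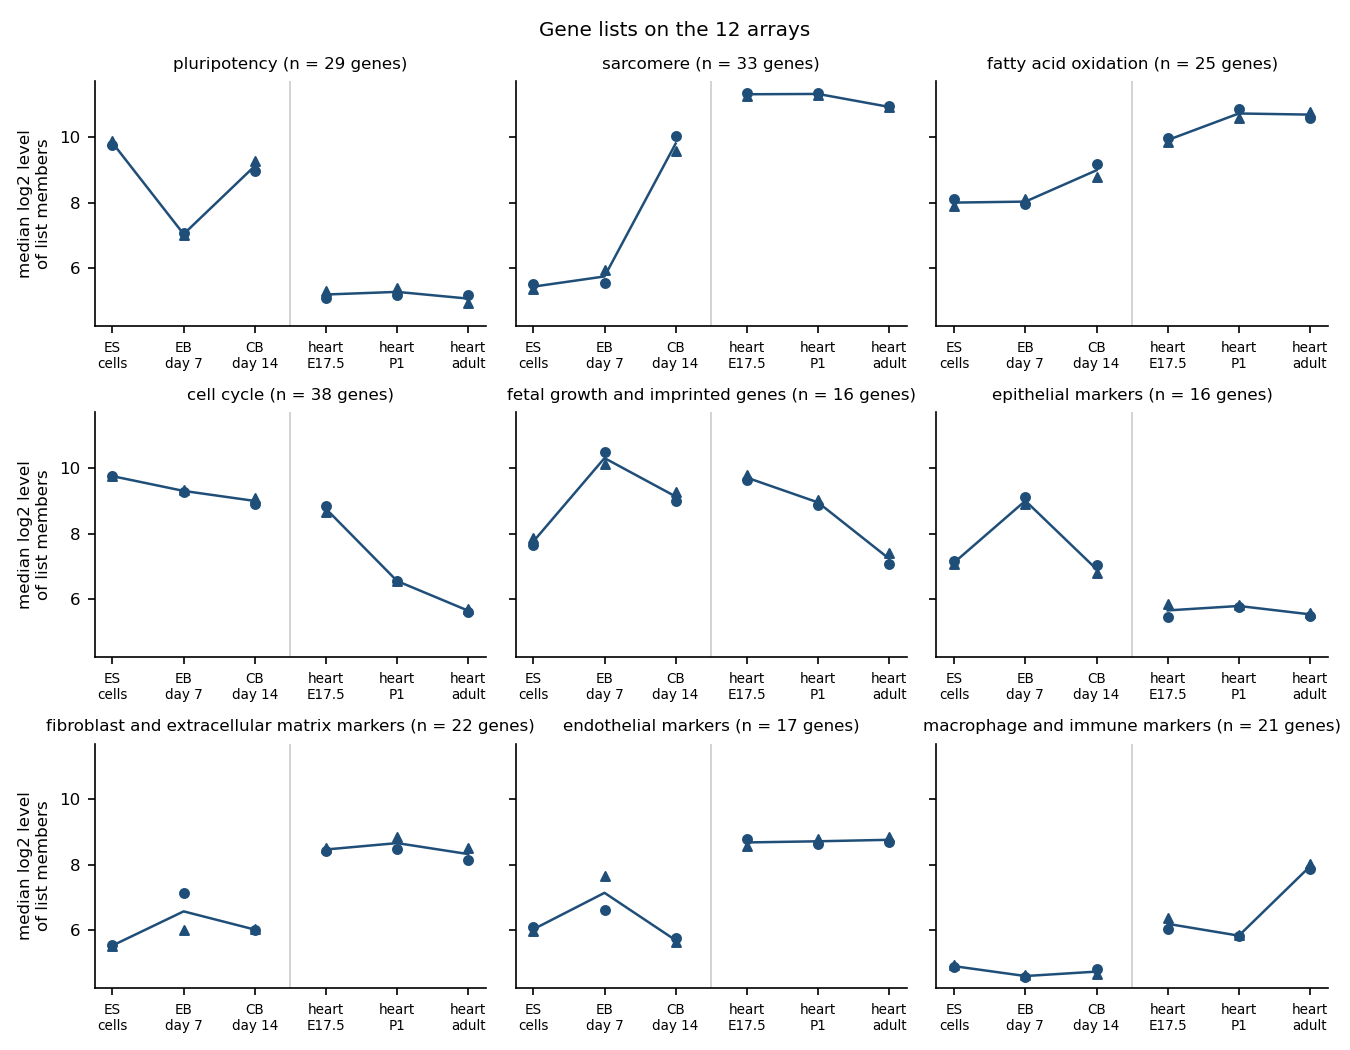
Median log2 gene level of 9 gene lists (vertical axis) in the 6 groups (horizontal axis), with circles for replicate 1, triangles for replicate 2 and lines joining the means of the cultured groups and of the hearts. Pluripotency genes were lowest in culture in embryonic bodies, where 23 of 29 fell against ES cells, and 23 of 29, not all the same genes, rose from embryonic to cardiac bodies.

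The comparison of cardiac bodies with embryonic bodies asks what follows in culture as heart muscle forms. Myl2 (transcript cluster 10525343), the ventricular myosin light chain, rose by 7.08 ± 0.20 (adjusted p = 2.75e-09), from 4.84 to 11.91. Myh6 rose by 6.89 ± 0.21 (adjusted p = 3.13e-09), the sarcomere gene Actn2 by 5.73 ± 0.18 and Tnnt2 by 5.28 ± 0.19. Of 33 sarcomere genes 27 rose and none fell, with 31 rising adjusted over the list alone; the median change was 3.84, and the camera adjusted p was 3.58e-45, or adjusted p = 0.028 with an estimated correlation. Myh7, the beta myosin heavy chain, changed by 1.66 ± 0.51 and was not called (adjusted p = 0.056). Pln, the regulator of the cardiac calcium pump, rose by 7.15 ± 0.24, the sodium-calcium exchanger gene Slc8a1 by 4.33 ± 0.30 and the calcium release channel gene Ryr2 by 3.51 ± 0.35. They were among 12 of 24 calcium handling genes that rose, or 13 with 1 falling adjusted over the list alone (camera adjusted p = 4.13e-13; adjusted p = 0.101 with an estimated correlation). The 2 CB arrays differed: 5 of these 24 genes were higher by over 1 in replicate 1 and none in replicate 2, and the median difference, replicate 1 minus 2, was 0.49 over sarcomere genes and -0.30 over pluripotency genes. Fatty acid oxidation genes rose in 14 of 25 cases, 17 adjusted over the list alone, with Cpt1a up by 3.01 ± 0.18 and Lpl by 2.94 ± 0.29 (camera adjusted p = 9.31e-16; adjusted p = 0.0709 with an estimated correlation). For the citrate cycle and oxidative phosphorylation 18 of 31 genes rose, 28 adjusted over the list alone; 11 rose without EB replicate 1 and 6 without CB replicate 1 (camera adjusted p = 9.8e-19; adjusted p = 0.101 with an estimated correlation).

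Pluripotency genes were higher again in cardiac bodies than in embryonic bodies. Pou5f1 rose by 2.58 ± 0.20 (adjusted p = 5.55e-06), from 8.49 to 11.07, and Nanog by 2.44 ± 0.17 (adjusted p = 2.69e-06). Of the 29 pluripotency genes 23 rose, with a median change of 2.21; adjusted over the list alone 25 rose and 1 fell (camera adjusted p = 1.54e-28; adjusted p = 0.0232 with an estimated correlation). Afp and Alb, genes of yolk sac and liver, rose by 4.94 ± 0.24 and 4.47 ± 0.17. Their list of 19 endoderm markers had 6 rises and 3 falls, also when adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.46 with an estimated correlation), with 6 falls without EB replicate 2 and 1 without CB replicate 2. Epithelial markers fell, with Krt18 down by 3.94 ± 0.24 and Cldn6, a tight junction gene, by 3.90 ± 0.21. None of the 16 rose and 11 fell, 13 adjusted over the list alone (camera adjusted p = 1.02e-12; adjusted p = 0.0311 with an estimated correlation). Kdr fell by 3.09 ± 0.26 and the endothelial receptor gene Tek by 2.69 ± 0.36. Among 17 endothelial markers 9 fell and 2 rose, 11 and 3 adjusted over the list alone (camera adjusted p = 1.69e-05; adjusted p = 0.211 with an estimated correlation). Of 16 fetal growth and imprinted genes 9 fell, 10 adjusted over the list alone, with Peg3 down by 2.74 ± 0.45 (camera adjusted p = 8.88e-08; adjusted p = 0.0512 with an estimated correlation). Igf2 itself changed by -0.55 ± 0.41 and was not called.

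Of 42 splicing regulators 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.535; adjusted p = 0.934 with an estimated correlation); 3 fell without EB replicate 1 and 2 without EB replicate 2 or either CB array. Esrp1, an epithelial splicing factor, fell by 1.84 ± 0.19 (adjusted p = 3.76e-05), while Rbm20 and Rbm24, splicing factors of striated muscle, rose by 1.89 ± 0.21 and 2.05 ± 0.33. In this comparison 1085 of 19920 genes rose and 1280 fell, 672 and 685 of them by at least 2-fold. The 2365 calls became 1217 without CB replicate 1 and 1422 without CB replicate 2.

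At exon level, 2 genes of the actin cytoskeleton carried the calls between cardiac and embryonic bodies. A probe set of Palld (10578856), which encodes the actin-associated protein palladin, rose in index by 5.53 ± 0.39 (adjusted p = 0.0109), with mean signals of 9.93 ± 0.83 and 3.05 ± 0.90 (SD, n = 2) while the gene rose by 1.35. Another Palld probe set (10578855), chosen after its values were seen, rose in index by 3.29 ± 0.22 (adjusted p = 0.0109). In Mical2, an actin-oxidizing enzyme, 1 probe set (10556406) rose by 3.57 ± 0.30 (adjusted p = 0.0363), with means of 8.34 and 2.43. The gene rose by 2.33, with means of 8.53 and 6.2, so the probe set lay close to its gene in cardiac bodies. Its signal in embryonic bodies was below the array medians and not tested against background. This call therefore does not by itself show a change of exon use. The Mical2 call was not made with the replicate block. All 3 calls lay in genes whose level changed by more than 1. These 3 were all the limma calls among 93817 probe sets; diffSplice made 131, and 3441 had an unadjusted p under 0.05. The count was 6 without ES replicate 1 or ES replicate 2, 37 without EB replicate 1, and 0 without either CB, E17.5 or P1 array; the adjusted p reached 0.132 for Palld without CB replicate 1 and 0.237 for Mical2 without EB replicate 2.

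Cardiac bodies were compared with ES cells to ask for the net change over the culture. Pln (transcript cluster 10363157) rose by 8.19 ± 0.24 (adjusted p = 1.73e-09), from 3.63 to 11.83, the first below the array medians and not tested against background, so that the size of the rise is uncertain, and Actc1, cardiac actin, by 7.47 ± 0.38 (adjusted p = 1.33e-07). Myh6 rose by 7.01 ± 0.21, Tnnt2 by 6.60 ± 0.19 and the stretch-responsive gene Ankrd1 by 7.13 ± 0.33. Of 33 sarcomere genes 31 rose, the same number as when adjusted over the list alone, and 2 were not called; the median change was 4.32 and the camera adjusted p 1.14e-55, or adjusted p = 0.0232 with an estimated correlation. Cardiac transcription factors rose in 16 of 24 cases, 19 adjusted over the list alone, with Tbx20 up by 4.79 ± 0.58 and Gata6 by 3.64 ± 0.29 (camera adjusted p = 2.9e-18; adjusted p = 0.0311 with an estimated correlation); 10 rose without CB replicate 1. The muscle splicing factors Rbm24 and Rbm20 rose by 3.31 ± 0.33 and 2.47 ± 0.21, and Esrp1 changed by -0.15 ± 0.19 and was not called. Among 24 calcium handling genes 13 rose, 15 adjusted over the list alone (camera adjusted p = 2.34e-19; adjusted p = 0.0552 with an estimated correlation). Fatty acid oxidation genes rose in 15 of 25 cases, 16 adjusted over the list alone, with Cd36, a fatty acid transporter, up by 4.71 ± 0.50; 9 rose without CB replicate 1 (camera adjusted p = 2.82e-14; adjusted p = 0.0832 with an estimated correlation).

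Pluripotency genes changed less against ES cells in cardiac bodies than in embryonic bodies, with medians of -0.54 and -2.69. Pou5f1 was at a mean of 11.07 against 11.83 and fell by 0.77 ± 0.20 (adjusted p = 0.031), a call that 6 arrays each ended when left out, with adjusted p up to 0.189 without CB replicate 1. Nanog fell by 0.80 ± 0.17 (adjusted p = 0.00947; 0.0961 without CB replicate 1). Of 29 pluripotency genes 12 fell and none rose; adjusted over the list alone 15 fell and 1 rose (camera adjusted p = 8.93e-06; adjusted p = 0.17 with an estimated correlation). The fall count was 6 without ES replicate 1, 4 without ES replicate 2, 4 without CB replicate 1 and 7 without CB replicate 2. Klf5 and Klf4, Krüppel-like factors of the ES cell network, fell by 1.66 ± 0.25 and 1.64 ± 0.28. Afp and Alb rose by 5.15 ± 0.24 and 4.28 ± 0.17; 8 of 19 endoderm markers rose, 11 adjusted over the list alone, and 5 without ES replicate 2 (camera adjusted p = 4.15e-09; adjusted p = 0.103 with an estimated correlation). Over all genes 1233 rose and 719 fell, 822 and 315 of them by at least 2-fold. The 1952 calls became 1004 without ES replicate 1, 927 without ES replicate 2 and 883 without CB replicate 1.

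Exon calls between cardiac bodies and ES cells included known targets of heart splicing. A probe set of Capzb (10509631), which encodes the beta subunit of the actin capping protein of the Z-disc, rose in index by 4.35 ± 0.41 (adjusted p = 0.0102), with mean signals of 9.70 ± 0.79 and 5.14 ± 0.59 (SD, n = 2) while the gene changed by 0.22. In Ttn, which encodes titin, 31 probe sets were called, with the largest change (10484186) at 5.25 ± 0.50 (adjusted p = 0.0112). That probe set rose with its gene: its means were 11.03 and 2.13, and those of the gene 9.76 and 6.11. Signals were not tested against background, so this call does not by itself show a change of exon use. For Slc25a3, the mitochondrial phosphate carrier, 1 probe set (10371885) rose by 2.03 ± 0.24 (adjusted p = 0.0287) with means of 11.96 and 9.40. The Slc25a3 call was not made with the replicate block. The index of a Mybpc3 probe set (10473822), in cardiac myosin binding protein C, fell by 4.39 ± 0.25 (adjusted p = 0.00114): its means were 11.24 and 10.11 while the gene rose by 5.51. In ES and EB arrays the probe set read 9.81 to 10.41 where the gene read 5.83 to 6.18, so it hardly followed its gene. Of 93071 probe sets 71 were higher and 31 lower in index, in 46 genes, and 85 of the 102 lay in genes whose level changed by more than 1. Without CB replicate 1 the count was 7 and the adjusted p was 0.113 for Capzb, 0.162 for Ttn and 0.251 for Slc25a3, whereas Mybpc3 was called without each array in turn. The count was 40 without ES replicate 2, 20 without CB replicate 2, 38 without either E17.5 array, 31 without either P1 array and 42 without either adult array.

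**Figure D2:**
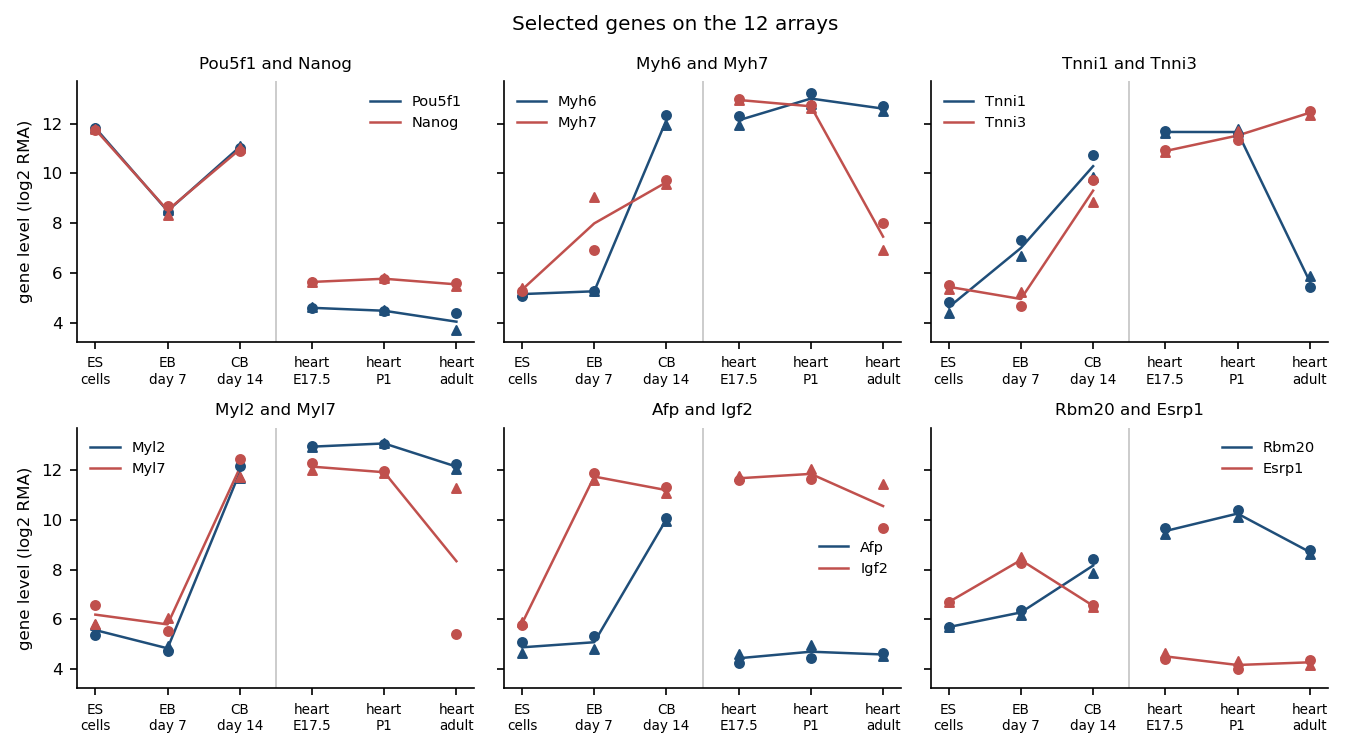
Log2 gene level (vertical axis) of 6 pairs of genes in the 6 groups (horizontal axis), with circles for replicate 1, triangles for replicate 2 and lines joining group means. Pou5f1 had means of 11.83, 8.49 and 11.07 in the cultured groups, and Tnni1 went from 11.67 at P1 to 5.65 in adult hearts.

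The P1 and E17.5 hearts were compared to ask what changes around birth. Ucp3 (transcript cluster 10555378), a mitochondrial carrier induced by fatty acids, rose by 3.35 ± 0.18 (adjusted p = 3.19e-06), from 4.61 to 7.96. The fatty acid transporter gene Slc27a1 rose by 2.58 ± 0.18 (adjusted p = 9.77e-06), Pdk4, which restrains glucose oxidation, by 2.57 ± 0.22, and Angptl4, an inhibitor of lipoprotein lipase, by 2.90 ± 0.21. Of 25 fatty acid oxidation genes 12 rose and none fell, with 16 rising adjusted over the list alone; the median change was 0.68 (camera adjusted p = 2.55e-18; adjusted p = 0.0552 with an estimated correlation). Of 7 adipose markers Cidea and Fabp4 rose as well, also when adjusted over the list alone (camera adjusted p = 0.0108; adjusted p = 0.166 with an estimated correlation), and Cidea fell from P1 to adult hearts (adjusted p = 0.000732). Genes of glucose uptake and lactate export fell: Slc2a1 by 2.05 ± 0.28 and Slc16a3 by 2.19 ± 0.29. Of 20 glycolysis genes 6 fell, 10 adjusted over the list alone, and 3 fell without E17.5 replicate 1 or E17.5 replicate 2 (camera adjusted p = 8.98e-06; adjusted p = 0.211 with an estimated correlation). Cell cycle genes fell together, with the mitotic kinesin gene Kif11 down by 3.90 ± 0.41 (adjusted p = 0.000142), the checkpoint kinase gene Bub1 by 3.73 ± 0.35 and the proliferation marker Mki67 by 2.58 ± 0.31. Of 38 cell cycle genes 36 fell, also when adjusted over the list alone, with a median change of -2.29 (camera adjusted p = 9.61e-57; adjusted p = 0.0232 with an estimated correlation). Some erythroid markers fell too: Alas2, of heme synthesis, fell by 3.01 ± 0.69 (adjusted p = 0.0259) and Slc4a1, of the red cell membrane, by 2.22 ± 0.50 (adjusted p = 0.0224), 2 of 11 markers, also when adjusted over the list alone, with a median of -0.88 (camera adjusted p = 0.0168; adjusted p = 0.669 with an estimated correlation). Without E17.5 replicate 1 only 1 fell, and none without E17.5 replicate 2 or P1 replicate 1. How far a change in blood content bears on the other falls was not tested.

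Among contractile genes few were called at birth. Myh7 changed by -0.25 ± 0.51, Tnni1, the troponin I of fetal heart and slow skeletal muscle, by -0.00 ± 0.30 and Tnni3, the adult cardiac troponin I, by 0.62 ± 0.27, none of them called. Myh6 rose by 0.87 ± 0.21 (adjusted p = 0.0339; 0.265 without E17.5 replicate 2), and 2 of 33 sarcomere genes rose, or 3 with 1 falling adjusted over the list alone (camera adjusted p = 0.0302; adjusted p = 0.68 with an estimated correlation); 4 rose and 2 fell without P1 replicate 1. The 2 P1 arrays were the least alike of any group, and 9 of 38 cell cycle genes were higher by over 1 in replicate 1 than in replicate 2, Kif11 with 6.21 and 4.36. In total 414 genes rose and 607 fell, 224 and 406 of them by at least 2-fold. The 1021 calls became 303 without E17.5 replicate 1, 353 without E17.5 replicate 2, 544 without P1 replicate 2 and 3056 without P1 replicate 1. At exon level limma called 0 of 94468 probe sets, with 6361 at an unadjusted p under 0.05 and 204 calls by diffSplice; it called 20 without E17.5 replicate 2 and 1 without CB replicate 1 or CB replicate 2.

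The comparison of adult with P1 hearts asks how the heart matures after birth. Tnni1 (transcript cluster 10350149) fell by 6.01 ± 0.30 (adjusted p = 1.41e-07), from 11.67 to 5.65, and Tnni3 rose by 0.92 ± 0.27 (adjusted p = 0.0229; 0.113 without adult replicate 1). Myh7 fell by 5.24 ± 0.51 (adjusted p = 1.6e-05), while Myh6 changed by -0.41 ± 0.21 and was not called. Xirp2, an actin-binding protein of intercalated discs, rose by 4.63 ± 0.28. Of 33 sarcomere genes 5 rose, 10 fell and 18 were not called, with the same counts adjusted over the list alone, and 3 rose without adult replicate 1 (camera adjusted p = 0.0822). Fetal growth and imprinted genes fell in 12 of 16 cases, 13 adjusted over the list alone, with Mest down by 4.47 ± 0.24 and Igf2r by 2.45 ± 0.25; the median change was -1.71 (camera adjusted p = 2.65e-08; adjusted p = 0.0485 with an estimated correlation). The elastin gene Eln fell by 4.09 ± 0.27 and the collagen genes Col1a1 and Col3a1 by 3.40 ± 0.40 and 3.36 ± 0.60. In the list of 22 fibroblast and matrix genes 9 fell and 5 rose, 10 and 5 adjusted over the list alone (camera adjusted p = 0.0734), with 3 rising without P1 replicate 2 or either adult array. Of 38 cell cycle genes 21 fell, and 21 fell with 1 rising adjusted over the list alone (camera adjusted p = 7.19e-09; adjusted p = 0.123 with an estimated correlation).

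Immune genes were higher in adult hearts. H2-Aa (transcript cluster 10450154) and Cd74, genes of antigen presentation, rose by 5.21 ± 0.24 (adjusted p = 6.26e-08) and 4.71 ± 0.25 (adjusted p = 2.08e-07), and the macrophage gene Lyz2 by 3.39 ± 0.22. Of 21 macrophage and immune markers 18 rose and none fell, 19 rising adjusted over the list alone, with a median change of 1.46 (camera adjusted p = 1.54e-13; adjusted p = 0.0232 with an estimated correlation). Among splicing regulators Rbfox1, which promotes neuronal and muscle exons, rose by 2.39 ± 0.23 (adjusted p = 1.24e-05), Rbm20 fell by 1.55 ± 0.21 (adjusted p = 0.000165), Srsf5 by 2.87 ± 0.26 and Hnrnpf by 2.44 ± 0.16. In this list of 42 genes 6 rose and 16 fell, 6 and 17 adjusted over the list alone (camera adjusted p = 0.0155; adjusted p = 0.624 with an estimated correlation). The 2 P1 arrays differed here, with 7 of the 42 higher by over 1 in replicate 1 and none in replicate 2. Fatty acid oxidation genes went both ways, 6 up and 7 down of 25, the same counts as adjusted over the list alone (camera adjusted p = 0.406), with Lpl up by 1.48 ± 0.29 and Acadvl down by 1.32 ± 0.19.

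Atrial genes separated the 2 adult hearts. Myl7, the atrial myosin light chain, was at 5.42 in replicate 1 and 11.27 in replicate 2, and it fell by 3.58 ± 1.22 against P1 (adjusted p = 0.0425; 0.239 without adult replicate 1). Of 10 atrial markers 4 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.135). Without adult replicate 1, 3 rose and 1 fell; the fall count was 8 without adult replicate 2, and 1 without either P1 array.

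**Figure D3:**
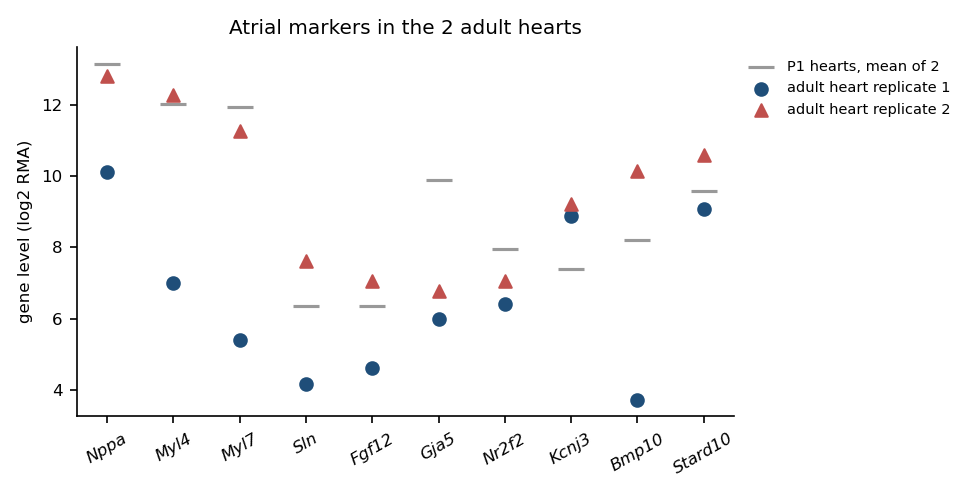
Log2 gene level (vertical axis) of 10 atrial markers (horizontal axis) in adult heart replicate 1 (circles) and replicate 2 (triangles), with dashes for the mean of the 2 P1 hearts. All 10 were lower in adult replicate 1, from 8.89 against 9.22 in Kcnj3 to 3.74 against 10.14 in Bmp10.

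Adult and P1 hearts differed in 6018 genes, 3098 higher and 2920 lower in adults, 1661 and 1264 of them by at least 2-fold. Calls reached dim signals too: of the 4980 genes of lowest mean level 12.59% were called, against 0.18% between P1 and E17.5, and of 12146 transcript clusters without a symbol 16.1% were called, against 0.1%. How adult hearts were obtained and processed is not given in the sources used here, so a batch and the adult group cannot be told apart.

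The comparison of adult with E17.5 hearts asks for the whole change from late gestation. Tnni1 fell by 6.01 ± 0.30 (adjusted p = 5.6e-08), Myh7 by 5.50 ± 0.51 (adjusted p = 5.54e-06), and Tnni3 rose by 1.54 ± 0.27 (adjusted p = 0.000773). Of 33 sarcomere genes 9 rose and 10 fell, 9 and 12 adjusted over the list alone (camera adjusted p = 0.67); 5 fell without E17.5 replicate 1 and 6 without E17.5 replicate 2. Cell cycle genes fell in 37 of 38 cases, also when adjusted over the list alone, with Kif11 down by 4.86 ± 0.41 and a median change of -2.95 (camera adjusted p = 2.11e-29; adjusted p = 0.028 with an estimated correlation). Mest fell by 5.14 ± 0.24 and the growth-restraining gene Cdkn1c by 3.11 ± 0.18, among 14 of 16 fetal growth and imprinted genes that fell, also adjusted over the list alone (camera adjusted p = 7.13e-10; adjusted p = 0.0351 with an estimated correlation). Of 21 immune markers 20 rose, 21 adjusted over the list alone, with C1qb, a complement gene of macrophages, up by 3.49 ± 0.30 (camera adjusted p = 9.07e-12; adjusted p = 0.0232 with an estimated correlation). Fatty acid oxidation genes rose in 16 of 25 cases and fell in 2, 17 and 2 adjusted over the list alone, with Ucp3 up by 3.02 ± 0.18 and Pdk4 by 2.89 ± 0.22 (camera adjusted p = 0.000178; adjusted p = 0.344 with an estimated correlation). Of 7 adipose markers 4 rose, Adipoq, Fabp4, Lep and Plin1, or 5 adjusted over the list alone, and 2 without E17.5 replicate 1 (camera adjusted p = 0.0263; adjusted p = 0.211 with an estimated correlation). Glycolysis genes fell in 13 of 20 cases and rose in 1, 13 and 2 adjusted over the list alone, with Slc16a3 down by 2.56 ± 0.29 and Slc2a1 by 2.14 ± 0.28 (camera adjusted p = 3.11e-05; adjusted p = 0.217 with an estimated correlation). The tissue inhibitor gene Timp4 rose by 5.72 ± 0.21 and the retinoid receptor gene Rxrg by 5.62 ± 0.19.

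Splicing regulators fell more often than they rose between E17.5 and adult hearts: 21 of 42 fell and 7 rose, 22 and 8 adjusted over the list alone (camera adjusted p = 0.000387; adjusted p = 0.434 with an estimated correlation). The rise count was 4 without E17.5 replicate 1. Rbfox1 rose by 2.99 ± 0.23 (adjusted p = 1.12e-06), while Hnrnph1 fell by 3.17 ± 0.37, Hnrnpf by 3.05 ± 0.16 and Srsf5 by 2.98 ± 0.26. Over all genes 3600 rose and 3588 fell, 1848 and 1982 of them by at least 2-fold.

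At exon level the adult hearts stood apart from the younger ones. A probe set of Cacna1c (10547324), the cardiac L-type calcium channel, fell in index by 5.60 ± 0.78 against P1 (adjusted p = 0.00352), with mean signals of 2.96 ± 0.25 in adults and 9.01 ± 0.11 at P1 (SD, n = 2), and by 5.11 ± 0.78 against E17.5 (adjusted p = 0.00418). That of Itpr3 (10443155), an intracellular calcium release channel, rose by 6.07 ± 0.54 (adjusted p = 0.000872) and 6.96 ± 0.54 (adjusted p = 0.000634). Its mean was 10.79 in adults and 4.98 at P1, while the gene was at 6.63 and 6.88. In Ank2, an ankyrin of heart muscle membranes, a probe set (10501972) fell in index by 3.41 ± 0.41 against P1 (adjusted p = 0.00217), and in Arpc5, of the actin-nucleating complex, another (10350685) fell by 5.41 ± 0.26. The Arpc5 probe set had means of 7.8 in adults and 12.87 at P1, while the gene had 9.52 and 9.18. Whether the Itpr3 and Arpc5 probe sets read only their own gene was not tested. In Fhod3, a formin of the sarcomere, a probe set (10454382) rose by 3.74 ± 0.59 against E17.5 (adjusted p = 0.00474). Some of the largest changes against E17.5 came from probe sets already high at P1, unlike Itpr3. That of Hadhb (10520477) rose by 6.78 ± 1.33. Its arrays were at 3.23 and 1.9 at E17.5, 8.39 and 9.13 at P1, and 8.87 and 8.85 in adults. A Ttn probe set (10484049) rose by 6.89 ± 0.85. Its arrays were at 1.86 and 4.48 at E17.5, 8.87 and 8.21 at P1, and 10.08 and 10.01 in adults. Neither was called between P1 and E17.5.

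Against P1, 5712 of 94451 probe sets were higher and 7023 lower in index in adult hearts, in 5210 of 8037 genes; against E17.5, 7864 of 94308 were higher and 7682 lower, in 5557 of 7931 genes. Of the 12735 calls against P1, 2876 lay in genes whose level changed by more than 1. Among probe sets of the dimmest 25% of genes, 20.7% had an unadjusted p under 0.05 against P1 and 21.1% against E17.5, compared with 6% between P1 and E17.5. The count against P1 was 5755 without P1 replicate 1 and 5478 without P1 replicate 2, and that against E17.5 was 6835 without E17.5 replicate 2.

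**Figure D4:**
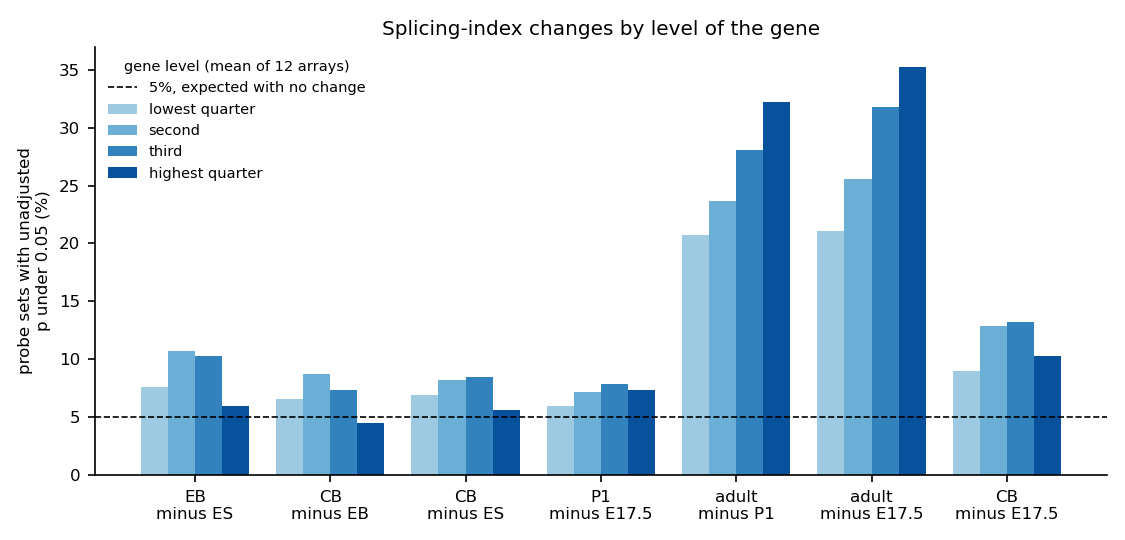
Percent of probe sets with an unadjusted p under 0.05 for the splicing index (vertical axis), for each comparison (horizontal axis), with bars for 4 classes of mean gene level from lowest (light) to highest (dark) and a dashed line at 5%. The adult comparisons lay between 20.7% and 35.2% in every class and the other comparisons between 4.5% and 13.2%.

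Cardiac bodies were compared with E17.5 hearts to ask how cardiomyocyte cultures differ from fetal heart tissue. Pou5f1 was at a mean of 11.07 in cardiac bodies, 11.83 in ES cells and 4.6 in E17.5 hearts. How far undifferentiated cells among the cardiac bodies bear on the falls and rises of this comparison was not tested. Myh6 had means of 12.15 ± 0.29 and 12.14 ± 0.27 (SD, n = 2) and was not called (change 0.02 ± 0.21, adjusted p = 0.976). Myh7 fell by 3.31 ± 0.51 (adjusted p = 0.000541), Ttn by 1.92 ± 0.32 and Nppa, the atrial natriuretic peptide gene, by 4.01 ± 0.58. Of 33 sarcomere genes 22 fell and none rose, 24 falling adjusted over the list alone (camera adjusted p = 5e-10; adjusted p = 0.193 with an estimated correlation); 11 fell without CB replicate 2 and 14 without E17.5 replicate 1. Calcium handling genes fell in 15 of 24 cases, 16 adjusted over the list alone and 9 without CB replicate 2, with Casq2, the calcium store protein, down by 4.19 ± 0.25 (camera adjusted p = 5.12e-08; adjusted p = 0.193 with an estimated correlation). Of 25 fatty acid oxidation genes 19 fell, 20 adjusted over the list alone (camera adjusted p = 6.14e-11; adjusted p = 0.112 with an estimated correlation). Cardiac transcription factors fell in 12 of 24 cases and rose in 1, 14 and 1 adjusted over the list alone, with Hey2, of ventricular muscle, down by 4.31 ± 0.32 (camera adjusted p = 1.65e-05; adjusted p = 0.164 with an estimated correlation); 5 fell without CB replicate 2 and 7 without either E17.5 array.

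Genes of the other cell types of the heart were low in cardiac bodies. Dcn (transcript cluster 10365974), a proteoglycan of fibroblasts, fell by 6.55 ± 0.49 (adjusted p = 2.04e-06) and Col1a2 by 5.41 ± 0.39; 20 of 22 fibroblast and matrix genes fell, 21 adjusted over the list alone, with a median change of -2.78 (camera adjusted p = 2.92e-18; adjusted p = 0.0446 with an estimated correlation). Emcn and Cdh5, endothelial surface genes, fell by 5.85 ± 0.62 and 4.16 ± 0.28, with 16 of 17 endothelial markers falling, also adjusted over the list alone (camera adjusted p = 2.53e-15; adjusted p = 0.0552 with an estimated correlation). Of 21 immune markers 11 fell, 13 adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.0502 with an estimated correlation). Pluripotency genes stood higher in 27 of 29 cases, also adjusted over the list alone, with a median of 3.88 (camera adjusted p = 5.64e-34; adjusted p = 0.0232 with an estimated correlation). Dppa5a rose by 7.99 ± 0.29 (adjusted p = 6.86e-09) and Pou5f1 by 6.47 ± 0.20 (adjusted p = 5.24e-09). Epithelial markers rose in 11 of 16 cases and fell in 1, 12 and 3 adjusted over the list alone, with Cdh1 up by 3.92 ± 0.25 (camera adjusted p = 4.78e-06; adjusted p = 0.0956 with an estimated correlation). Of 19 endoderm markers 9 rose and 1 fell, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000234; adjusted p = 0.266 with an estimated correlation), with Afp up by 5.59 ± 0.24. Among splicing factors Esrp1 and Ptbp1, a repressor of neuronal and muscle exons, rose by 2.03 ± 0.19 and 1.27 ± 0.21, and Rbm20 fell by 1.39 ± 0.21. Esrp1 had means of 6.55 in cardiac bodies and 6.7 in ES cells, Ptbp1 10.52 and 10.94, and Rbm20 8.16 and 5.69. In all 2406 genes were higher and 2312 lower in cardiac bodies, 1239 and 1213 of them by at least 2-fold, and the 4718 calls became 2462 without CB replicate 2, 2942 without E17.5 replicate 1 and 2946 without E17.5 replicate 2.

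Cardiac bodies and E17.5 hearts also differed in exon signals. While the gene Myh6 changed by 0.02, 1 of its probe sets (10419921) fell in index by 6.28 ± 0.29 (adjusted p = 0.00066), with mean signals of 5.55 ± 0.75 and 11.81 ± 0.07 (SD, n = 2). Probe sets of Inpp5d (10348246), a phosphatase of blood cells, and Eif2s2 (10488809), a translation initiation factor, fell by 6.91 ± 0.53 and 5.91 ± 0.30. That of Inpp5d read 4.11 and 2.25 in ES cells, 6.24 and 6.53 in embryonic bodies and 2.48 and 2.63 in cardiac bodies. That of Eif2s2 read 5.72 and 5.53, 4.65 and 4.8, and 4.57 and 3.95, so it was lower than at E17.5 in all cultured groups. For the core splicing factor gene Prpf8, 1 probe set (10378599) rose by 5.51 ± 0.56 (adjusted p = 0.0129; 0.1 without E17.5 replicate 2). It was low in the E17.5 arrays alone, at 3.03 and 2.82 against 8.08 to 10.49 in the other 10, so that E17.5 stood apart for Prpf8 rather than cardiac bodies. A probe set of Pkm (10585938), pyruvate kinase, fell by 1.93 ± 0.24 (adjusted p = 0.0256; 0.129 without CB replicate 1), a call that diffSplice did not make. Of 94068 probe sets 70 were higher and 154 lower in index, in 194 genes. Among 182 of these 224 calls in genes at or above the median level in all 6 groups, the ES cell index lay nearer to cardiac bodies than to E17.5 heart in 178, or 97.8%, the P1 index in 32, or 17.6%, and the adult index in 67, or 36.8%. The EB index did so in 160, or 87.9%. These shares cannot tell whether the calls come from the ES line, undifferentiated cells or cardiomyocytes. Strains are not given in the sources used here. The count was 111 without either ES array, 18 without CB replicate 1, 69 without CB replicate 2, 59 without E17.5 replicate 2 and 52 without either P1 array.

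**Figure D5:**
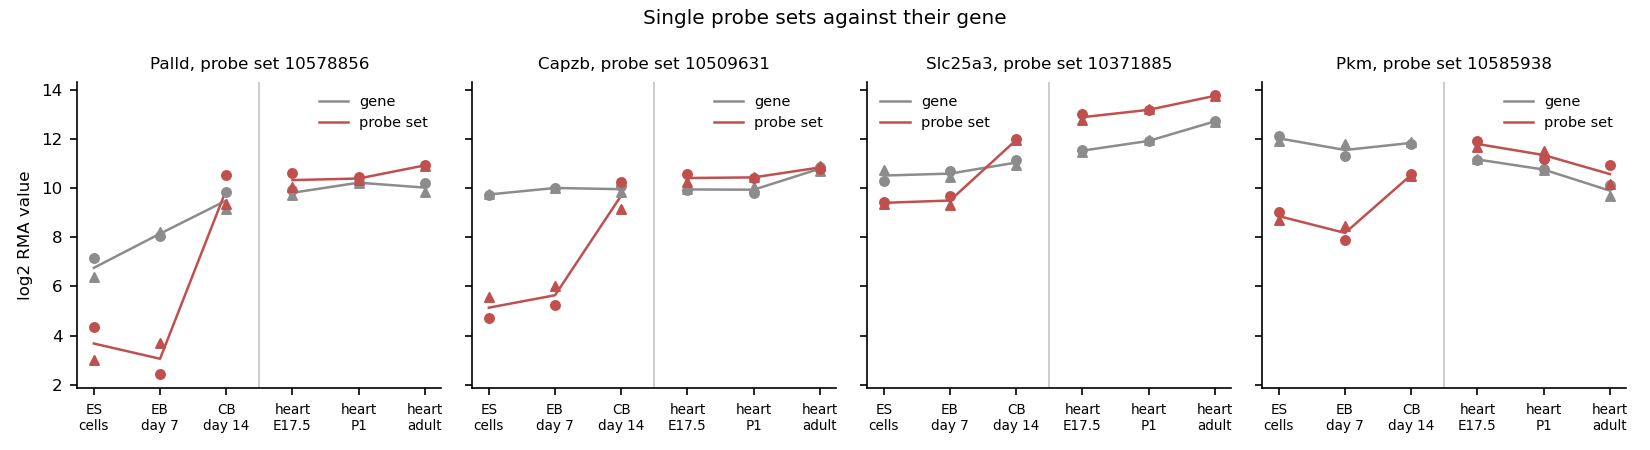
Log2 signal (vertical axis) of 4 probe sets, in red, and of their genes, in grey, in the 6 groups (horizontal axis), with circles for replicate 1, triangles for replicate 2 and lines joining group means. The Palld probe set had means of 3.05 in embryonic bodies and 9.93 in cardiac bodies, and the Capzb probe set 5.14 in ES cells and 9.70 in cardiac bodies.

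The list of alternatively spliced heart genes was fixed to ask whether known heart splicing targets carry the exon calls. Between cardiac bodies and ES cells 7 of 52 list genes had a called probe set against 39 of 8111 other genes (Fisher's exact test, two-sided, p = 1.24e-08, adjusted over 7 comparisons 8.68e-08), among them Ttn, Tnnt2, Tpm1, Capzb and Slc25a3. Of the 102 calls 85 lay in genes whose level changed by more than 1; the Tpm1 probe set (10594673) had means of 8.97 and 9.10 while the gene rose by 3.80. The calls became 0 by limma when the test took only genes changed by at most 1, or a filter at the 70th percentile, where the full test had 3526 at an unadjusted p under 0.05 and diffSplice 264. Between embryonic bodies and ES cells it was 3 of 49, namely Tnnt2, Tpm1 and Ank3, against 25 of 7958 (exact p = 0.000634, adjusted 0.00148). The named probe sets of these 3 genes were not called with the median of the other probe sets as the gene level, and the 35 calls of that comparison became 0 with the replicate block and without any one of 10 of the 12 arrays (unadjusted 4259, diffSplice 300). In adult hearts it was 55 of 64 against 5155 of 7973 in the comparison with P1 (exact p = 0.000196, adjusted 0.000686), and 56 of 64 against 5501 of 7867 with E17.5 (exact p = 0.00146, adjusted 0.00256). List genes had a median of 17 to 20 tested probe sets and other genes 9. Among genes with 8 to 40 tested probe sets the exact p was 0.174 with P1 and 0.192 with E17.5, but 0.000115 between cardiac bodies and ES cells. There 4 of 41 list genes had a call against 27 of 4836 others, without matching for the change of gene level. The Tnnt2 probe set with the largest change (10350175) read 11.09 and 11.74 in ES cells where the gene read 5.99 and 6.29, so it hardly followed its gene. In the other comparisons Pkm was the single list gene of 63 with a call between cardiac bodies and E17.5 hearts, and 0 of 57 and 0 of 65 list genes had a limma call between cardiac and embryonic bodies and between P1 and E17.5 hearts.

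Changes in culture and in the maturing heart were set side by side, cardiac bodies minus ES cells against adult minus E17.5 hearts. Genes that rose in both included the contractile and energy genes Tnni3, Cox6a2, Cox8b and Lpl, with Cox8b, a muscle subunit of cytochrome oxidase, up by 3.80 and 2.90. In total 371 genes rose in both, where 222.8 would meet by chance if all genes were alike and 254.3 among genes of similar level, and 223 fell in both, against 129.5 and 157.4. Another 282 rose in culture and fell in the heart, against 222.1 and 360, and 124 went the other way, against 129.9 and 142.7. Without a fold threshold neither opposite class thus exceeded chance at similar level. At 2-fold or more, 157 rose in both against 76.3 and 94.6, and 31 fell in both against 31.3 and 30.7. There 131 rose in culture and fell in the heart against 81.8 and 139.5, and 42 went the other way against 29.2 and 34.7. Across genes, which are not independent replicates, the changes correlated at r = 0.049 and rho = 0.083. Of 75134 probe sets tested in both, 3 were called in the same direction, 1 higher and 2 lower, where 5.5 and 2.4 would meet by chance with all alike, and 6 and 4 in opposite directions against 6.1 and 2.2.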

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

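The counts of list genes without each array and the chance counts by level were chosen after the results were seen, and all other alternatives before the data were examined. No call of the 7 comparisons or of the named genes reversed under any alternative. Gene counts stayed within 1.5 times the reported count with the replicate block (3963, 2206, 1837, 885, 5812, 7000 and 4520 in the order of the comparisons), the level filter, quantile normalization, the trend in the prior and the mean of transcript clusters. With the median of exon-level values they did so except for P1 minus E17.5, with 581 genes in place of 1021. Leaving out some array ended 149 of 617 named gene calls and 30 of 56 named probe set calls, among them all 10 in embryonic bodies minus ES cells and both in cardiac minus embryonic bodies; over the repeats, 762 ended a call, 8291 left the result the same and 49 turned the direction of a change called in neither. The exon-level calls are limited by the 2 arrays per group. Dim signals were not tested against background, which leaves calls of dim probe sets and the size of gene changes from or to dim levels uncertain.

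For embryonic bodies minus ES cells the 35 probe sets became 0 with the replicate block, 706 with no filter, 0 with the 70th percentile filter, 0 in genes changed by at most 1, 300 with diffSplice and 3 with the median of the other probe sets. For cardiac minus embryonic bodies the 3 became 133 with no filter, 0 in genes changed by at most 1 and 131 with diffSplice. For cardiac bodies minus ES cells the 102 became 662 with no filter, 0 with the 70th percentile filter, 0 in genes changed by at most 1, 264 with diffSplice and 66 with the median of the other probe sets. A 0 here is limma's count; the unadjusted counts and those of diffSplice were 4259 and 300, 3441 and 131, and 3526 and 264. For P1 minus E17.5 the 0 became 204 with diffSplice. Adult minus P1 went from 12735 to 20099 with no filter and 6930 with the 70th percentile filter, and adult minus E17.5 from 15546 to 25367 and 7898. For cardiac bodies minus E17.5 the 224 became 102 with the replicate block, 869 with no filter, 115 with the 70th percentile filter, 119 in genes changed by at most 1 and 1372 with diffSplice. With the replicate block the calls of Mical2 in cardiac minus embryonic bodies, Slc25a3 in cardiac bodies minus ES cells and Pkm in cardiac bodies minus E17.5 were also lost. No filter tests more probe sets and the stricter ones fewer; the cause of the other changes was not tested.

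Of 168 pairs of list and comparison 91 were called with the preset correlation and 15 with the estimated one. Of the 594 genes called in the same direction in culture and in the heart 188 changed at least 2-fold in both: 157 rose in both where 76.3 would meet by chance, or 94.6 among genes of similar level, and 31 fell in both against 31.3 and 30.7, so the excess of shared falls was lost. At 2-fold, 131 rose in culture and fell in the heart against 81.8 and 139.5, and 42 went the other way against 29.2 and 34.7. The 3 shared probe sets became 6 at an adjusted p under 0.05 whatever the size. Among genes with 8 to 40 tested probe sets, 86% of the alternatively spliced heart genes had a call in adult minus P1 and 90% in adult minus E17.5, no longer past the threshold (exact p = 0.174 and 0.192).

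With each array left out in turn, where a lone array is assumed to vary like the other groups, gene counts ran from 2384 to 4958 for embryonic bodies minus ES cells, 1217 to 3226 for cardiac minus embryonic bodies, 883 to 2539 for cardiac bodies minus ES cells, 303 to 3056 for P1 minus E17.5, 4529 to 6116 for adult minus P1, 5010 to 8004 for adult minus E17.5 and 2462 to 5669 for cardiac bodies minus E17.5. Probe set counts ran, in that order, from 0 to 159, 0 to 37, 7 to 92, 0 to 20, 5478 to 12116, 6835 to 15123 and 18 to 258.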

Other observations

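Of the tests below, 3 were set before their result was seen: those of sequence variants, of undifferentiated cells and of atrial tissue; the tests of array response, gene-level change, exchanged labels and heart muscle genes were chosen only after the result was seen, as was the use of heart splicing genes with 8 to 40 probe sets, an alternative set earlier, as a test of an explanation.

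Small RNA genes were looked at after the data were seen, and no enrichment of calls among them was tested. Mir208a, which lies within a cardiac myosin gene, rose by 2.96 ± 0.44 between E17.5 and P1 (adjusted p = 0.0019), and Mir1a-1, a muscle microRNA gene, fell by 3.87 ± 0.31 between P1 and adult hearts (adjusted p = 3.97e-06). Of 300 microRNA genes 44 rose and 1 fell in embryonic bodies against ES cells, 3 rose and 35 fell from embryonic to cardiac bodies, and 16 rose and 57 fell from P1 to adult hearts, where 20.6%, 11.9% and 30.2% of all genes were called. Of 54 genes of small nucleolar RNAs, which guide RNA modification, 24 rose and 7 fell from P1 to adult hearts, with Snord47 up by 4.89 ± 0.31 and Snord82 by 4.79 ± 0.29, and 29 were higher and 1 lower in cardiac bodies than at E17.5.

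Among 38 cell cycle genes 9 fell and 2 rose in embryonic bodies against ES cells, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0035; adjusted p = 0.419 with an estimated correlation). In cardiac bodies 11 fell and 1 rose, 26 and 1 adjusted over the list alone (camera adjusted p = 5.14e-12; adjusted p = 0.0872 with an estimated correlation). The fall counts were 4, 2, 4 and 3 without ES replicate 1, ES replicate 2, EB replicate 1 and EB replicate 2 in the first comparison, and 4, 3, 4 and 7 without ES replicate 1, ES replicate 2, CB replicate 1 and CB replicate 2 in the second; 1 rose in the first without ES replicate 1, and none in the second without ES replicate 1 or either CB array. Ccne1, a cyclin of DNA replication start, fell by 2.24 ± 0.20 in embryonic bodies (adjusted p = 7.48e-06) and by 1.21 ± 0.20 in cardiac bodies, Ccne2, the other cyclin E gene, rose by 0.87 ± 0.19 in embryonic bodies (adjusted p = 0.0061; 0.0666 without ES replicate 1) but was among the genes that fell in cardiac bodies, and Ccnd2, a cyclin of growth signals, rose by 2.45 ± 0.28 and 1.21 ± 0.28, the second with an adjusted p of 0.0149 that was 0.174 without ES replicate 1.

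The 2 EB arrays also differed in tissue markers chosen after their values were seen: Ttr, of yolk sac and liver, was at 10.44 in replicate 1 and 5.87 in replicate 2, Foxf1, of lateral mesoderm, at 10.06 and 6.21, and Emcn at 5.14 and 8.02. In P1 hearts the cohesin gene Stag2, chosen the same way, was at 8.51 in replicate 1 and 5.85 in replicate 2. Nipbl and Atrx, also chosen after, were lower in replicate 2 too, while Gpnmb was higher there, at 7.74 against 5.11. Of 66 alternatively spliced heart genes, 15 were higher by over 1 in P1 replicate 1 and 0 in P1 replicate 2. The cause of this difference between the P1 arrays was not tested. Fabp4, a lipid carrier of fat and capillaries, rose by 1.92 ± 0.23 from E17.5 to P1 and fell by 4.18 ± 0.23 in cardiac bodies against E17.5.

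Adult hearts had called probe sets in 5210 of 8037 genes against P1. A large change of the gene as a whole was argued against, since 77.4% of the calls against P1 lay in genes whose level changed by at most 1. Sequence variants between the mice stay open: of 8131 probe sets called the same way in both adult comparisons, in genes at or above the median in all 6 groups, all 3 cultured groups lay nearer to adult hearts in 2.6%, below the 10% set beforehand as counting against variants, but that bound was dropped after the value was seen, because 88.7% lay nearer to the younger hearts, which an ES line sharing their variants would also give, and strains are not given in the sources used here. A difference in how probe sets respond on the adult arrays may contribute, since 20.7% of probe sets in dim genes had an unadjusted p under 0.05, and a batch and the adult group cannot be told apart. A change of splicing during maturation stays open and was not decided by the heart splicing genes (exact p = 0.174).

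Pluripotency genes were higher in cardiac than in embryonic bodies, 23 of 29. Exchanged labels were argued against, since 27 of 33 sarcomere genes rose from embryonic to cardiac bodies. Undifferentiated cells among the cardiac bodies may account for the pattern, but the test could not decide this. It picked 210 genes higher in ES cells than in embryonic bodies by at least 2 in replicate 1. Of these 202, or 96.2%, were higher in cardiac than in embryonic bodies in replicate 2, against 38.2% of all genes. Because the genes were picked for low levels in embryonic bodies, a high share could arise from other causes too. Genes picked as high in embryonic bodies moved back as well, 84.9% of 410 being lower in cardiac bodies. Undifferentiated cells would give this too, but these genes were also picked by their level in embryonic bodies. A pluripotency program active in differentiated cells was not excluded and was not tested.

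Atrial genes differed between the 2 adult hearts, Myl7 with 5.42 and 11.27. An array-wide difference in heart muscle genes was argued against, since the 31 sarcomere genes outside the atrial list differed by a median of 0.199, against 0.2 for all genes. Less atrial tissue in replicate 1 may account for the pattern: the 8 atrial markers other than Myl7 and Nppa were lower there by a median of 1.97. Genes outside the atrial list differed too, among 28 genes that differed by at least 2. Of these, chosen after their values were seen, Hamp was at 3.6 and 10.87, Vsig4 at 5.49 and 9.12, and Ngp at 3.57 and 6.99. Whether atrial tissue accounts for them was not tested. A difference between the animals stays open and was not tested.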
